A study of Rattus norvegicus with 6 samples.

How the data were processed

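Libraries were made from total RNA with a modified SMART-seq2 protocol, which primes reverse transcription at the poly(A) tail and amplifies full-length cDNA by PCR, per the labels' protocols. The submitters' processing notes name STAR 2.5.3a and RSEM 1.3.0. The genome build is not given in the sources used here. The authors deposited a table of gene counts, in whole numbers, for the whole series.

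The heading of each count column was compared with the whole title and the whole description of each sample, ignoring case and punctuation. A code that formed only part of a title would not have matched under this rule. All 6 columns of per-sample values were left out because none matched a sample. An edgeR quasi-likelihood comparison of 3 exposed with 3 control animals, and tests of gene lists, had been planned before the data were examined and were not run. Before the columns were left out, the range and total of each were looked at once to find out what unit the table held.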

Results

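RNA was sequenced from the vestibular ganglion, which holds the cell bodies of the neurons that carry balance signals from the inner ear, of 6 male Long-Evans rats. The labels put 3 rats in a control group that drank plain water. The other 3 rats drank water with 20 mM 3,3'-iminodipropionitrile (IDPN), a compound toxic to the inner ear, for 4 weeks. The ganglia of both sides of an animal were pooled. The exposed rats share a number in their sample titles that no control carries. A difference tied to that number could not be told apart from one tied to IDPN. The comparison this design implies is gene expression in the ganglia of exposed against control rats.

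That comparison was not made. The count table has 6 columns of values, each headed by a library code, and the labels of the 6 samples carry other codes beside the treatment. The number of columns whose code matched the whole title or description of a sample was 0. No column was therefore assigned to an animal or to a group, and its place in the table was not used in place of a label. No expression level, fold change or p-value is reported for any gene, and nothing is said here about whether IDPN changed gene expression.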

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

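The number of count columns matched to a sample was also 0 under the 2 other matching rules tried, which were chosen after the column headings were seen. The first rule was not part of the plan either. One looked for the code anywhere in a sample's labels, and the other looked for its digits in the title or description. No alternative settings for the comparison of exposed with control animals were run, because no column was assigned to a group.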
